A study of Caenorhabditis elegans with 20 samples.

How the data were processed

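Total RNA sequencing was deposited for 20 libraries of day 1 adult Caenorhabditis elegans, 4 from each of 5 strains. The strains were the wild type N2, a pgrn-1 null strain (CF3050), and 3 strains that express granulin 1 (AWK33), granulin 2 (AWK43) or granulin 3 (AWK107) in the null background. Progranulin is a secreted precursor protein that is cleaved into granulins, and pgrn-1 is its gene in this nematode. Per the labels' protocols, animals were synchronised by egg lay, RNA was purified with a Qiagen miRNeasy kit and libraries were made with an Illumina TruSeq Stranded Total RNA kit. Groups were taken from the strain label, because the group label gave the name AWK33 to all 3 granulin strains. Each granulin was carried by 1 strain, so an effect of a granulin and any other difference of its strain are confounded. The labels do not say that the 4 libraries of a strain came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates are numbered in accession order. Within a strain this number follows the order of the letters in the sample names, and it was not used to pair libraries. Sample names carry letters, A to D for wild type, granulin 1 and granulin 3 and E to H for the null and granulin 2, and their meaning is not given in the sources used here. If the letters stand for batches, the null against wild type, granulin 1 and 3 against the null, granulin 2 against wild type, granulin 2 against 1 and granulin 3 against 2 are fully confounded with them.

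The authors deposited 1 table per library with log2 depth-scaled counts (log2 CPM) for 46778 genes, of which 19725 are protein-coding and 15363 are piRNA genes. The submitters' processing notes list STAR, HTSeq, edgeR, limma and the genome build ce11, without versions, order or settings. The annotation behind the deposited values and the strand setting of the counting are not given in the sources used here. One floor value, -5.05 log2 CPM, was shared by all files and stands for 0 reads, and the linear values above it were whole multiples of a step that differed between libraries. Reads were recovered from these steps as whole numbers, with an implied prior count of 2 scaled to library size and no further scaling between libraries. Within a tolerance of 0.01 reads, at least 99.99% of the values above 0 in every library came out whole, and 7 values in all did not. A simulated set of 935560 values was recovered exactly. Totals ranged from 48279370 to 128776517 reads per library. Gene symbols, types and coordinates came from Ensembl release 115 for the same build, which held 46603 of the IDs, 43818 of them with a symbol. The other 175 IDs held at most 0.0544% of a library's reads. No pair of replicates agreed within sampling noise (smallest chi-square per degree of freedom 157), so no library was counted as a copy of another.

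Because the deposited unit is log2 and not counts, the quasi-likelihood test of edgeR and the DESeq2 test chosen earlier were not run. The test used in their place was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust moderation, on log2 CPM with a prior count of 2 recomputed from the recovered reads. This choice was made before any calls were seen. Genes were kept with at least 0.177 CPM (10 reads at the median library size) in at least 4 libraries and 15 reads in all, which left 15737 genes, 14861 of them protein-coding. Scaling factors were trimmed means of M values (TMM, trimming 30% of ratios and 5% of levels). All 20 libraries were fitted together with 1 mean per strain, and each comparison is the first strain minus the second. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are on the log2 (CPM plus prior) scale, which understates the change of low genes, and they are given ± the moderated standard error (SE) with n = 4 libraries per strain. Where all libraries of a strain had 0 reads, a bound on the fold was computed from a floor of 3 reads per library, which covers counting error only.

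Gene lists, the rule for naming genes, the comparisons and most alternatives were fixed before the data were examined. The 32 lists covered lysosomal proteases, other lysosomal hydrolases, lysosomal membrane and trafficking, the vacuolar ATPase, autophagy, vitellogenins, the heat shock, endoplasmic reticulum and mitochondrial stress responses, immune effectors, C-type lectins, the intracellular pathogen response (pals genes), detoxification, oxidative stress, fatty acid metabolism, the respiratory chain, mitochondrial DNA genes, ribosomal proteins, the proteasome, cuticle collagens, apoptosis, insulin signalling, sperm, oocytes, germline meiosis, embryonic differentiation, neurons, neuropeptides, muscle, intestine, hypodermis and histones. Each was tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 32 lists, and again with the correlation estimated from the data. The values were those of the gene test, where voom values had been chosen for count files, and voom values were run as an alternative. Named genes are the 6 with the highest and the 6 with the lowest log2 fold change among genes past the threshold that have a symbol, a mean of at least 1 log2 CPM and no overlap between the 4 libraries of each strain, for the null against wild type and each granulin strain against the null. Added to them are 3 members with the lowest p for up to 6 lists that passed, and always pgrn-1, hlh-30, asp-3 and lmp-1. For the other 6 comparisons the 2 highest and the 2 lowest are named. The values of 1 sperm gene that met this rule are not reported here.

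Alternatives were relative log expression scaling, voom, no filter on low genes, protein-coding genes alone, a fit of the 2 strains alone, each library left out in turn, and a block for the letter that the sample names share. Others were added after the data had been seen. For each library the slope of its gene deviations on transcript length was computed over 10303 genes. On data simulated for granulin 1 against the null (15734 genes), the test called 0% of 67 genes changed 1.5-fold, 8.96% of 67 genes changed 2-fold and 51.5% of 66 genes changed 4-fold, with 4 calls among unchanged genes. Return toward wild type and overlap between granulin strains were computed with the null libraries split 2 and 2, because those libraries enter both comparisons. The simulation of unchanged groups and the treatment of genes at 0 reads in the return share were each corrected once after first values had been seen. Reads of near-identical genes (msp, nspd, nspg, his and col families, and pseudogenes) can be exchanged or lost in counting, and values of these genes are uncertain. The same holds for overlapping and antisense genes, because the strand setting is not known. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.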

Results

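The series asked how each of 3 granulins, expressed without progranulin, changes the transcriptome of day 1 adult nematodes. It held 4 libraries each of wild type, the pgrn-1 null and the granulin 1, granulin 2 and granulin 3 strains. Total reads per library were 49262671 to 55184445 in wild type, 51870116 to 64353087 in the null, 48951123 to 63655561 in granulin 1, 49951656 to 108912781 in granulin 2 and 48279370 to 128776517 in granulin 3. Reads of ribosomal RNA genes took between 0.45% and 52.7% of a library, and were above 20% in wild type replicate 4 (44.8%), granulin 1 replicate 3 (25.9%), granulin 2 replicate 3 (52.7%) and granulin 2 replicate 4 (25%). The trend of gene levels with transcript length also differed within strains. Granulin 1 replicate 3 fell by 1.03 log2 units per doubling of length, and granulin 3 replicates 2 and 3, null replicate 1 and granulin 2 replicate 2 had slopes of -0.42, -0.33, -0.41 and -0.38. In the other 15 libraries the slope lay between -0.15 and 0.37.

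**Figure D1:**
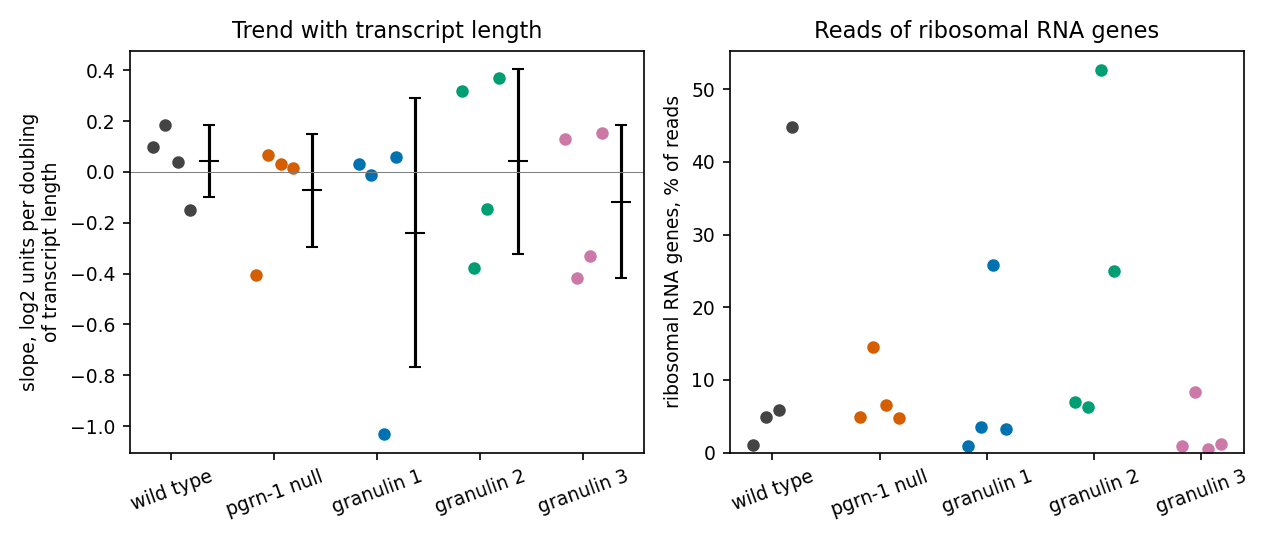
Left, slope of gene deviations in log2 units per doubling of transcript length, with points for the 4 libraries of each strain and a black bar for the mean ± SD. Right, reads of ribosomal RNA genes as a percent of all reads in each library; granulin 1 replicate 3 lies at -1.03 on the left, and granulin 2 replicate 3 at 52.7% on the right.

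The progranulin gene pgrn-1 (WBGene00011936, chromosome I, 11701631 to 11703698, ce11) followed the labels in every library. Wild type had 18.8 ± 12.2 CPM (SD, n = 4) and 527 to 871 reads. The null had 0.207 ± 0.11 CPM (SD, n = 4) and 6 to 32 reads. Levels were 443 ± 395 CPM in granulin 1, 200.5 ± 60.3 CPM in granulin 2 and 348 ± 68.3 CPM in granulin 3 (SD, n = 4 each), which is 23.6, 10.7 and 18.5 times the wild-type mean. The granulin 1 mean rests on replicate 3, at 1035 CPM, with 221 to 283 CPM in the other 3. Without it granulin 1 had 246 ± 32.7 CPM (SD, n = 3), 13.1 times wild type and below granulin 3. The wild-type mean was 12.7 ± 2.18 CPM (SD, n = 3) without replicate 4, at 36.9 CPM. The log2 fold change was -6.25 ± 0.47 for the null against wild type (limma, Benjamini-Hochberg adjusted p = 1.49e-07). Against the null it was 10.66 ± 0.47 in granulin 1 (adjusted p = 7.33e-12), 9.79 ± 0.47 in granulin 2 (adjusted p = 5.52e-11) and 10.63 ± 0.47 in granulin 3 (adjusted p = 7.8e-12). Gene totals do not tell which part of pgrn-1 the reads covered.

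**Figure D2:**
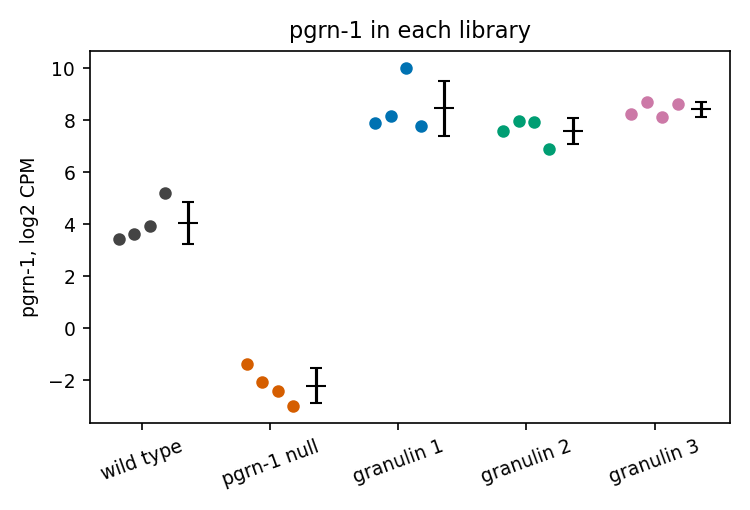
Level of pgrn-1 in log2 CPM in each of the 20 libraries (points) of the 5 strains, with the mean ± SD of 4 libraries as a black bar. The null libraries average -2.21 and wild type 4.05, and the granulin strains average between 7.59 and 8.46.

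On the first principal component (37.5% of the variance) all granulin 2 and granulin 3 libraries were positive, between 26.8 and 135.5, and all libraries of the other strains were negative, between -85.6 and -14.5. The second component (26.97%) ran from -84.6 in granulin 2 replicate 4 to 187.1 in granulin 1 replicate 3, and its next highest values were 81.2 in granulin 3 replicate 2 and 53.7 in null replicate 1.

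**Figure D3:**
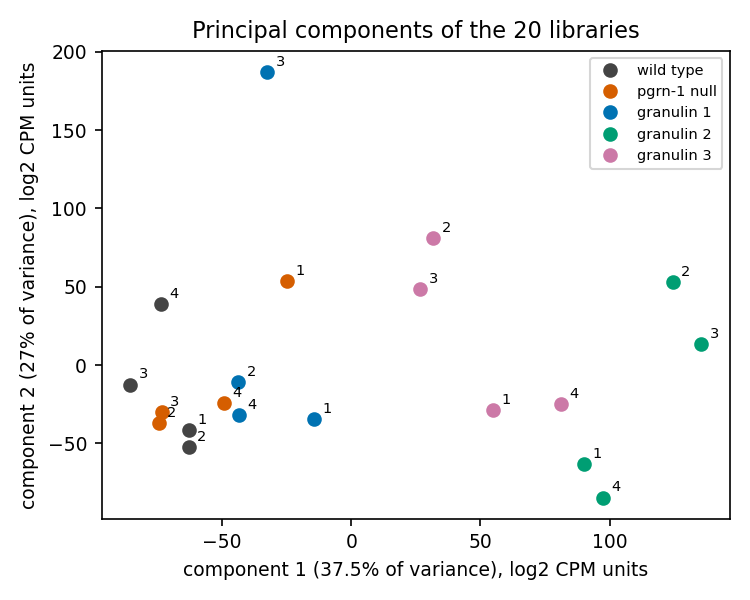
First and second principal components of log2 CPM over the tested genes, 1 point per library and 1 colour per strain. Granulin 2 and granulin 3 lie above 0 on the first component, and granulin 1 replicate 3 stands apart on the second at 187.1.

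Besides pgrn-1, the named genes that fell in the null against wild type included an F-box gene and a non-coding RNA. These strains carry different sets of letters in their sample names (E to H and A to D), so their differences cannot be told apart from any batch that the letters stand for. The same holds for granulin 1 and 3 against the null and granulin 2 against wild type. Exceptions are genes that also differ between strains with the same letters, such as F56A4.3, with reads in wild type and 0 in granulin 1 and 3, and F11C3.1, Y38E10A.14 and pgrn-1, which passed in granulin 1 or 3 against wild type. Y102A5C.36, T16H12.2, C04G6.15 and B0511.11 were likewise low in the null but not in granulin 2, which has the same letters. The F-box gene fbxa-192 fell by 4.07 ± 0.38 on the log2 scale (adjusted p = 4.81e-06), Y102A5C.36 fell by 3.03 ± 0.35 (adjusted p = 9.46e-05) and T16H12.2 fell by 2.63 ± 0.31 (adjusted p = 9.56e-05) in the null against wild type. The non-coding RNA C04G6.15 fell by 2.24 ± 0.34 (adjusted p = 0.0029) and B0511.11 fell by 2.12 ± 0.38 (adjusted p = 0.0156). In all 31 genes passed limma with Benjamini-Hochberg adjustment, 4 higher and 27 lower, against 19 with voom and 9 among protein-coding genes alone, 0 of them higher in either. The 4 higher genes were nspg-11 (1.74 ± 0.34, adjusted p = 0.0336), nspg-12 (1.70 ± 0.33, adjusted p = 0.0358), C33F10.1 (3.59 ± 0.73, adjusted p = 0.0435) and W10C8.6 (2.24 ± 0.45, adjusted p = 0.0391), the last 2 of which were outside the naming rule and chosen after their values were seen. At an unadjusted p under 0.05 there were 1622 genes, and the groups did not overlap for 10.4% of genes, where chance gives 2.86%. The count was 15 without wild type replicate 2, 18 without wild type replicate 3, and 19, 12, 17 and 20 without null replicates 1, 2, 3 and 4. It was 12 on the deposited scale, where nspg-11, nspg-12, T16H12.2, C04G6.15 and B0511.11 had no call and the median of all genes was shifted by 0.40. It was far larger in models chosen after the data were seen, all of which kept the 31 calls: 277 with the length slope as a covariate (71 higher) and 2224 and 2305 with 2 kinds of library weights (1204 and 1244 higher), the first of which stopped before it converged. With 1 library left out, nspg-11 lost its call in 7 of 8 cases, for every library of the 2 strains but wild type replicate 4 (adjusted p 0.0528 to 0.175), nspg-12 in 5, without wild type replicates 1, 2 or 3 or null replicates 1 or 2 (0.0771 to 0.176), B0511.11 in 4, without wild type replicates 1 or 2 or null replicates 2 or 3 (0.0528 to 0.103), and C04G6.15 without null replicate 2 (0.0735).

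The transcription factor gene hlh-30, which drives lysosomal and autophagy genes, had a log2 fold change of -1.25 ± 0.45 in the null (adjusted p = 0.345), the aspartyl protease gene asp-3 -0.43 ± 0.56 (0.9) and the lysosomal membrane protein gene lmp-1 -0.03 ± 0.44 (0.994). None of the 3 passed in any granulin strain against the null either, with adjusted p between 0.324 and 0.984. No member of the 24 lysosomal proteases, 31 other lysosomal hydrolases, 28 lysosomal membrane and trafficking genes, 21 vacuolar ATPase genes or 29 autophagy genes passed over all genes in the null. Adjusted over the list alone, 1 hydrolase gene, the nuclease gene crn-6 (named after its values were seen), was higher. List medians were -0.43, -0.07, 0.18, -0.14 and -0.06, and none of the 5 lists passed camera (adjusted p = 0.0893, 0.851, 0.116, 0.335 and 0.834).

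Cuticle and neuronal lists lay lower and sperm genes higher in the null than in wild type, without any member that passed over all genes. Camera with the preset correlation called the 80 sperm genes higher (median 0.89, adjusted p = 3.05e-12), and lower the 27 hypodermis and seam genes (median -1.14, 2.45e-10), 47 neuropeptides (-0.68, 4.29e-08), 138 cuticle collagens (-0.74, 6.74e-08), 34 neuron genes (-0.48, 8.79e-05), 34 core histones (-0.55, 0.000763) and 42 muscle genes (-0.49, 0.0428). The 33 proteasome genes were called higher (0.31, 0.00784). With an estimated correlation no list passed, the smallest adjusted p = 0.78 for hypodermis and adjusted p = 0.968 for the other 7 with an estimated correlation. Adjusted over the list alone, 10 hypodermis genes and 1 collagen gene, col-46, were lower, and 0 of the other lists' members passed. Examples with no call over all genes are wrt-2 at -2.57 ± 0.66 (adjusted p = 0.168), osm-8 at -2.997 ± 0.78 (0.179), col-46 at -2.14 ± 0.48 (0.0877), flp-2 at -1.38 ± 0.46 (0.292), unc-10 at -1.30 ± 0.39 (0.259), his-35 at -0.59 ± 0.23 (0.364) and the sperm gene ssp-16 at 2.06 ± 0.60 (0.25). The proteasome call was lost without wild type replicate 4 or null replicate 3 and the muscle call without either of these or null replicate 4. Without wild type replicate 4 the muscle median was -0.01, that of collagens -0.37 and that of neurons -0.22. The median of the sperm list was 0.50 without the 5 libraries with the lowest length slopes. In this and each of the other 6 comparisons with list tests, other splits of the same 8 libraries gave as many lists as the real one, with a highest count of 21 to 24.

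Beside pgrn-1, F11C3.1 (chromosome I, 14867924 to 14871365) rose by 4.46 ± 0.27 in granulin 1 over the null (adjusted p = 1.3e-09), from 154 to 350 reads to 3741 to 6230 reads. Y102A5C.36 rose by 3.95 ± 0.35 (adjusted p = 1.33e-06), fbxa-192 by 3.33 ± 0.38 (3.84e-05), the cilium gene dyf-3 by 3.1 ± 0.43 (0.000486) and bath-24, with a MATH domain, by 2.86 ± 0.30 (9.91e-06). The claudin-like gene clc-1 fell by 3.26 ± 0.33 (6.18e-06), F42A10.9 fell by 2.22 ± 0.47 (0.0308) and D1086.6 fell by 1.92 ± 0.39 (0.0222). Of 74 genes past the limma threshold 68 were higher and 6 lower, and 1176 had an unadjusted p under 0.05. The groups did not overlap for 4.55% of genes, with 2.86% from chance. The count was 42 without null replicate 2, 43 on the deposited scale and 25 in a fit of the 2 strains alone, where dyf-3, F42A10.9 and D1086.6 had no call. With the length covariate it was 138 (123 higher), and with the 2 kinds of library weights 667 and 824 (435 and 517 higher), all with the 74 calls kept. With 1 library left out, F42A10.9 lost its call in 7 of 8 cases, for every library of the 2 strains but granulin 1 replicate 3 (adjusted p 0.0527 to 0.144), and D1086.6 in 5, without granulin 1 replicates 1, 2 or 4 or null replicates 1 or 2 (0.072 to 0.111).

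No member of any of the 32 lists passed in granulin 1 against the null, neither over all genes nor adjusted over the list alone. Camera with the preset correlation called 13 lists. Higher were the 23 pals genes of the intracellular pathogen response (median 0.79, adjusted p = 1.29e-06), the collagens (0.44, 0.00107), the 89 immune effectors (0.37, 0.0105) and the sperm genes (0.37, 0.0105). Lower were the proteasome (-0.43, 1.29e-06), the 80 ribosomal proteins (-0.27, 2.68e-05), the 34 oocyte and eggshell genes (-0.87, 0.000466), the 47 nuclear genes of the respiratory chain (-0.24, 0.0069), 31 germline genes (-0.41, 0.00816), lysosomal membrane and trafficking (-0.28, 0.0226), 23 endoplasmic reticulum genes (-0.41, 0.0261), 6 vitellogenins (-1.13, 0.0349) and 28 apoptosis genes (-0.21, 0.0442). All 13 had adjusted p = 0.925 with an estimated correlation. Members with no call include pals-3 at 1.78 ± 0.53 (adjusted p = 0.264), col-111 at 1.37 ± 0.33 (0.0778), rpt-4 at -1.12 ± 0.43 (0.546), rpl-22 at -1.21 ± 0.49 (0.578) and cpg-3 at -1.05 ± 0.54 (0.712). Granulin 1 replicate 3, the library with the length slope of -1.03, had an oocyte list mean of -3.54 log2 units, against 0.745 to 0.854 in the other 3. The number of lists was 8 without it and 8 without null replicate 3. The pals, respiratory chain and ribosomal calls held whichever library was left out, 9 of the others were lost without granulin 1 replicate 3. Without this library 6 medians changed sign, oocyte genes to 0.36, germline genes to 0.20, endoplasmic reticulum to 0.12, vitellogenins to 0.06, apoptosis to 0.26 and immune effectors to -0.14, and the pals median was 0.26. The sperm call was lost without granulin 1 replicate 1 or 4 or null replicate 2. Null replicates 2, 3 and 4 also ended calls of vitellogenin, endoplasmic reticulum, apoptosis, collagen, germline or lysosomal membrane genes.

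Most sperm genes and many collagen genes rose in granulin 2. Of 80 sperm genes 72 rose and none fell against the null (73 higher adjusted over the list alone), with a median log2 fold change of 3.78. Examples are spe-54 at 4.49 ± 0.49 (adjusted p = 2.21e-06) and spe-19 at 4.30 ± 0.50 (3.56e-06), both needed for spermatogenesis. Of 138 cuticle collagens 68 rose and col-187 fell (77 and 1 adjusted over the list alone, median 1.91), among them col-109 at 5.69 ± 0.61 (1.65e-06), col-161 at 4.23 ± 0.49 (3.41e-06) and col-49 at 4.50 ± 0.55 (6.42e-06). Of 27 hypodermis genes 13 rose (13 adjusted over the list alone, median 1.09), with the adult collagen genes bli-1 at 4.44 ± 0.55 (7.7e-06) and bli-2 at 3.97 ± 0.61 (5.54e-05) and the patched-related gene ptr-23 at 2.56 ± 0.40 (6.29e-05). The genes dpy-7, rol-6, bli-1 and bli-2 belong to both the collagen and the hypodermis list. Without the 5 libraries with the lowest length slopes, 73 of 82 sperm genes and 80 of 139 collagens rose, with medians of 4.07 and 2.17.

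Among single genes in granulin 2, F15D4.5 (chromosome II, 13245376 to 13247774) rose by 7.59 ± 0.45 (adjusted p = 1.09e-09), from 30 to 82 reads in the null to 8958 to 20477. The neurosecretion gene unc-31 rose by 5.22 ± 0.36 (1.03e-08), the formin gene daam-1 by 5.13 ± 0.70 (1.95e-05), scrm-4 by 4.81 ± 0.30 (2.14e-09) and fmil-1 by 4.74 ± 0.74 (6.29e-05). The gene scrm-4 lies at 11680899 to 11682441 on chromosome I, near pgrn-1. ZC317.7 fell by 2.92 ± 0.54 (0.000334), C49C3.6 fell by 2.72 ± 0.27 (8.33e-07), acly-2, for ATP-citrate lyase, fell by 2.69 ± 0.92 (0.0407), mans-4 fell by 2.65 ± 0.44 (0.000132), clec-4 fell by 2.64 ± 0.51 (0.000574) and the lipase gene lipl-5 fell by 2.51 ± 0.55 (0.00169). In all, limma called 3407 genes, 2749 higher and 658 lower, and 30.3% of genes did not overlap between the groups, with 2.86% from chance. The count was 2247 on the deposited scale, which shifts the median of all genes by -0.18. There 237 genes were lower, and 188 were lower with the shared label letter as a block. With 1 library left out, between 313 (without granulin 2 replicate 4) and 864 (without null replicate 2) were lower. With the length covariate 3662 were higher and 2441 lower. The 2 kinds of library weights gave 3778 and 2121, and 4491 and 2902. The call of acly-2 was lost in 4 of 8 cases, without granulin 2 replicates 2 or 3 or null replicates 3 or 4 (adjusted p 0.085 to 0.122).

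Camera with the preset correlation called 12 lists in granulin 2 against the null. Sperm genes (adjusted p = 1.66e-25), collagens (4.37e-12) and hypodermis (0.00129) were higher. Lower were the proteasome (median -0.45, adjusted p = 0.00111), the respiratory chain (-0.38, 0.00111), ribosomal proteins (-0.23, 0.00422), autophagy (-0.45, 0.00944), oocyte genes (-0.78, 0.0144), germline genes (-0.33, 0.0168), the vacuolar ATPase (-0.21, 0.0245), apoptosis (-0.31, 0.0323) and endoplasmic reticulum genes (-0.38, 0.0336). With an estimated correlation the oocyte list had adjusted p = 0.755 and the other 11 adjusted p = 0.722. Among the 29 autophagy genes epg-2 rose and atg-4.2, atg-10, atg-13, atg-16.1 and atg-16.2 fell (1 and 5 adjusted over the list alone). In the vacuolar ATPase vha-1 and vha-18 fell (2 alone), and among germline genes him-8, htp-1 and syp-2 fell (0 alone). The gene rpl-42 (1 alone), the oocyte list's skr-8 and the apoptosis gene egl-1 (0 alone each) rose. All of these were named after their values were seen. In the proteasome, pas-5 fell by 0.95 ± 0.33 (adjusted p = 0.0434; 0 members adjusted over the list alone), and it lost this call in 6 of 8 cases, without granulin 2 replicates 1, 3 or 4 or null replicates 1, 3 or 4 (adjusted p 0.063 to 0.137). The respiratory chain gene ndab-2 (-1.04 ± 0.37, 0.0532) and the ribosomal gene rps-2 (-1.34 ± 0.62, 0.145) had no call. The number of lists was 7 without granulin 2 replicate 2, where vacuolar ATPase, endoplasmic reticulum, ribosomal, apoptosis, oocyte and germline calls were lost, and 19 without granulin 2 replicate 1. Without granulin 2 replicate 2 the germline median changed sign to 0.06, and the oocyte and ribosomal medians were -0.22 and -0.04. Null replicates 2 and 3 and granulin 2 replicate 3 also each ended calls of oocyte, apoptosis or endoplasmic reticulum genes.

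Sperm, neuropeptide, lectin and collagen genes were among those that rose in granulin 3, most of the list only for sperm. Of 80 sperm genes 49 rose and ssp-37 fell against the null (61 and 2 adjusted over the list alone, median 2.34), among them spe-11 at 4.02 ± 0.60 (adjusted p = 0.000273), nspd-9 at 3.48 ± 0.51 (0.000219) and spe-54 at 3.02 ± 0.49 (0.000508). Of 47 neuropeptide genes 11 rose and none fell (14 adjusted over the list alone, median 0.86), with flp-1 at 2.68 ± 0.47 (0.000844), nlp-18 at 2.35 ± 0.54 (0.00585) and flp-19 at 1.70 ± 0.38 (0.00453). Of 114 C-type lectins 28 rose (36 higher and 2 lower alone, median 0.59), and of 138 collagens 33 rose and col-68 and col-86 fell (39 and 3 alone, median 0.90), with col-161 at 2.79 ± 0.49 (0.000824), col-14 at 2.36 ± 0.44 (0.00145) and col-49 at 2.87 ± 0.55 (0.00174). Without the 5 libraries with the lowest length slopes, 69 of 82 sperm genes, 16 of 48 neuropeptides and 56 of 139 collagens rose. The list calls of sperm genes and lectins were lost with adjusted p = 0.488 with an estimated correlation, and those of neuropeptides and collagens with adjusted p = 0.793 with an estimated correlation. The call of flp-19 was lost without null replicate 2 (0.0683), and single genes given here for counts under 5 were named after their values were seen.

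Among single genes in granulin 3, the zinc transporter gene cdf-2 (chromosome X, 12464640 to 12466917) rose by 4.90 ± 0.29 (adjusted p = 6.17e-10), from 100 to 245 reads in the null to 4288 to 9254. This gene was not particular to granulin 3: it had 2128 to 8144 reads in granulin 2, and 134 to 287 in granulin 1. Others that rose in granulin 3 were nspd-1 (4.23 ± 0.83, 0.00199), pqn-31 (4.21 ± 0.69, 0.00058), Y102A5C.36 (4.04 ± 0.35, 4.93e-07) and cylc-1 (3.86 ± 0.78, 0.00256). Y38E10A.14 (chromosome II, 12623110 to 12624533) had 0 reads in all 4 granulin 3 libraries and 557 to 1979 in the null, and was at least 501-fold lower (adjusted p = 2.07e-11). Counts do not tell a loss of its expression from a difference in the genome of this strain. Y45F10C.2 fell by 3.33 ± 0.80 (0.00838), Y48E1B.8 fell by 2.97 ± 0.78 (0.0139), K08D9.9 fell by 2.83 ± 0.71 (0.0113), F42A10.9 fell by 2.58 ± 0.47 (0.00113) and T12D8.5 fell by 2.34 ± 0.48 (0.00277). In all 2006 genes passed limma, 1759 higher (87.7%) and 247 lower, and the groups did not overlap for 22.2% of genes, with 2.86% from chance. On the deposited scale, which shifts the median of all genes by 0.43, the split was 1996 higher (98.3%) and 35 lower. With the length covariate it was 2698 higher (61.3%) and 1702 lower. The 2 kinds of library weights gave 4158 and 2333, and 3707 and 1865. With 1 library left out, between 62 (without granulin 3 replicate 1) and 262 (without granulin 3 replicate 4) were lower. The share of higher genes thus depends on the model and on single libraries. The count was 1140 without null replicate 2, and Y48E1B.8 lost its call without granulin 3 replicate 3 (adjusted p = 0.0506).

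Camera with the preset correlation called 18 lists in granulin 3 against the null. Higher were sperm genes (adjusted p = 3.15e-17), neuropeptides (8.46e-05), collagens (0.000113), lectins (0.000734), pals genes (6 of 23 rose, 8 alone; median 0.77, 0.00508) and 176 detoxification genes (23 rose and gst-7 and cyp-25A1 fell, the same counts alone; 0.38, 0.0396). Lower were ribosomal proteins (median -0.68, 5.7e-10), the respiratory chain (-0.62, 1.38e-07), the proteasome (-0.52, 1.56e-05), oocyte genes (-0.84, 0.000734), germline genes (-0.54, 0.00137), 23 oxidative stress genes (-0.40, 0.00508), 96 fatty acid metabolism genes (-0.14, 0.0289), autophagy (-0.42, 0.0353), apoptosis (-0.18, 0.0385), 16 heat shock genes (-0.34, 0.045), core histones (-0.22, 0.0474) and 13 genes of the mitochondrial unfolded protein response (-0.64, 0.0491). With an estimated correlation the adjusted p was 0.488 for sperm, lectin, heat shock, mitochondrial stress, oxidative stress and respiratory chain genes, adjusted p = 0.722 for ribosomal proteins and adjusted p = 0.793 for the other 11. On the deposited scale the medians of heat shock, fatty acid, apoptosis and histone genes turned to 0.01, 0.23, 0.19 and 0.15, all below the shift of 0.43. Few members of the lower lists passed: the superoxide dismutase genes sod-2 and sod-3 fell (2 alone), as did htp-1 and syp-2 for meiosis (0 alone), his-32 and his-58 (0 alone), crn-5 and psr-1 for apoptosis (1 alone), timm-23 for mitochondrial stress (1 alone) and acdh-10, while elo-8, acs-15, acs-18, acdh-5 and acdh-8 of the fatty acid list rose (5 higher and 0 lower alone), all named after their values were seen. The ribosomal genes rpl-41.1 and rpl-22 fell by 1.65 ± 0.48 (0.0258) and fell by 1.58 ± 0.49 (0.0395), and asg-1, for a subunit of ATP synthase, fell by 1.24 ± 0.38 (0.036); adjusted over their lists alone 0 passed. With 1 library left out these 3 lost their calls in 4 (granulin 3 replicates 1 and 3, null replicates 1 and 3; adjusted p 0.0501 to 0.101), 7 (all but granulin 3 replicate 4; 0.0579 to 0.128) and 6 of 8 cases (granulin 3 replicates 1 to 3, null replicates 1, 3 and 4; 0.0665 to 0.114). The calls of pals, detoxification, fatty acid, autophagy, apoptosis, heat shock, histone and mitochondrial stress genes were each lost without at least 1 of granulin 3 replicates 2, 3 or 4 or null replicates 1 to 4, and the other 10 held. Without granulin 3 replicate 2 the apoptosis median changed sign to 0.04 and the oocyte median was -0.40. Leaving out 1 library at a time does not test granulin 3 replicates 2 and 3 together, which both have low length slopes. Their oocyte list means were -1.78 and -1.01, against 0.61 and 0.49 in replicates 1 and 4 and -0.67 to 1.03 in the null. Ribosomal means were -1.1 and -0.76 against -0.12 and 0.24, and respiratory chain means -0.88 and -0.75 against -0.11 and 0.24. The low values of these lists thus came mostly from replicates 2 and 3.

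**Figure D4:**
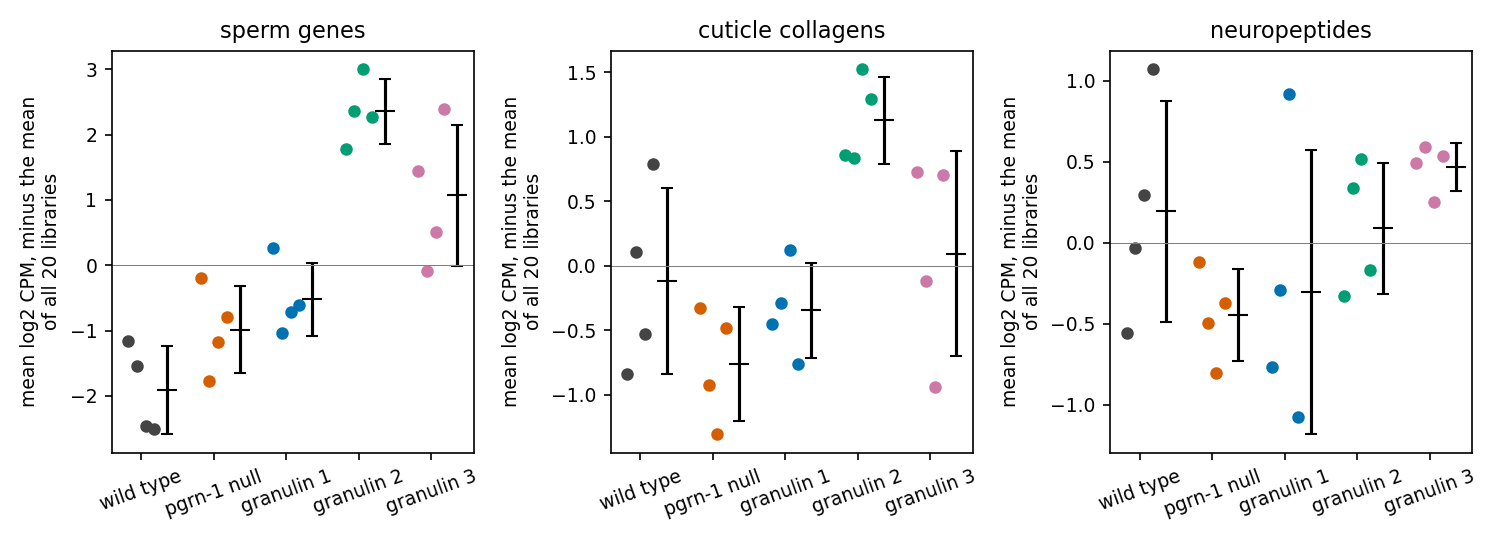
Mean log2 CPM of the sperm genes, cuticle collagens and neuropeptides in each library, after subtracting each gene's mean over all 20 libraries; points are libraries and the black bar is the mean ± SD of 4. The number of sperm genes that rose over the null was 72 in granulin 2 and 49 in granulin 3.

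Lists that passed in none of the granulin strains against the null included 34 neuron genes, of which 9 rose and snb-1 fell in granulin 2 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0676), and 14 genes of embryonic differentiation, of which ceh-27, tbx-37, tbx-38 and sdz-31 rose (5 alone, 0.0866). Of 31 other lysosomal hydrolases sul-2, aagr-4, aman-1 and lipl-6 rose and nuc-1, hex-1, gba-4 and lipl-5 fell in granulin 2 (4 and 4 alone, median -0.18, 0.206). Among 27 genes of insulin signalling daf-28 and lys-7 rose and dao-3 and sod-3 fell in granulin 3 (2 and 2 alone, median -0.21 and mean 0.02, tested lower, 0.315). No member of the 21 intestine genes or the 12 genes of mitochondrial DNA passed in granulin 1, 2 or 3 against the null, and of 42 muscle genes pat-2 rose in both granulin 2 and granulin 3, ttn-1 in granulin 2 (1 alone) and tni-1 in granulin 3 (2 alone). No lysosomal protease passed in granulin 2, and pcp-3 and cpr-8 of 24 rose in granulin 3 (1 alone). These members were named after their values were seen. Median, mean and test had the same sign in every list that passed camera in any of the 7 comparisons, and differed in some that did not, such as vitellogenins in granulin 2 (median 0.42, tested lower, adjusted p = 0.945).

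Set against wild type, the granulin 2 and granulin 3 strains kept high sperm transcripts. Of 80 sperm genes 72 rose in granulin 2 (74 adjusted over the list alone, median 4.95) and 64 in granulin 3 (66 higher and 1 lower alone, median 3.57); granulin 1 had 0 (36 higher alone, median 1.67). The medians were the same with ssp-36, at 0 reads in all wild-type libraries, set at its bound. In granulin 1, F11C3.1 rose by 4.55 ± 0.27 (adjusted p = 8.9e-10) and pgrn-1 by 4.41 ± 0.47 (1.97e-05), clc-1 fell by 3.50 ± 0.33 (2.92e-06) and D1086.6 fell by 2.23 ± 0.39 (0.0104). In granulin 2, F15D4.5 rose by 6.70 ± 0.45 (7.6e-09) and F27C1.1 by 6.36 ± 0.73 (1.92e-06), ZC317.7 fell by 3.71 ± 0.54 (1.98e-05) and Y46D2A.2 fell by 3.58 ± 0.36 (7.63e-07). In granulin 3, cylc-1 rose by 5.15 ± 0.78 (0.000133) and nspd-1 by 4.92 ± 0.83 (0.000288), Y38E10A.14 was at least 754-fold lower and Y48E1B.8 fell by 3.66 ± 0.78 (0.00222). Limma called 51 genes in granulin 1 (41 higher), 2885 in granulin 2 (2444 higher, 84.7%) and 1766 in granulin 3 (1677 higher), with 1413, 4378 and 3139 at an unadjusted p under 0.05. Genes without overlap were 4.15%, 21.6% and 15.1%, with 2.86% from chance. Without wild type replicates 1, 2 and 3 the granulin 1 count was 77 (47 higher and 30 lower), 33 and 29. It was 30 without granulin 1 replicate 1. With the shared label letter as a block it was 11 (5 higher and 6 lower), and 14 for the same libraries without the block. In a fit of the 2 strains alone it was 9 (4 higher and 5 lower), and pgrn-1 and D1086.6 had no call. The excess of higher genes in granulin 1 thus depends on the fit. On the deposited scale, which shifts the median of all genes by 0.47, 0.20 and 0.82 in the 3 comparisons, the granulin 2 split was 2348 higher (96.6%) and 84 lower and the granulin 3 count 2770. With the length covariate 3107 were higher and 1983 lower in granulin 2, and 2056 and 858 in granulin 3. The 2 kinds of library weights gave 3235 and 1762, and 4029 and 2598 in granulin 2. In granulin 3 they gave 2810 and 459, and 2564 and 278.

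Camera with the preset correlation called 17, 10 and 16 lists against wild type in granulin 1, 2 and 3, and none with an estimated correlation (smallest adjusted p = 0.703, 0.468 and 0.575 with an estimated correlation). In granulin 1 vitellogenins had a median of -2.20 (0 of 6 passed, all 6 lower adjusted over the list alone; camera adjusted p = 6.78e-05, adjusted p = 0.703 with an estimated correlation). The 12 mitochondrial DNA genes had a median of 0.81 (0.00222, adjusted p = 0.703 with an estimated correlation), a call lost without granulin 1 replicate 3 (median 0.07), in which mitochondrial reads were 8.09% of the library. Of the immune effectors clec-60, clec-86 and ilys-2 rose (6 alone; 0.50, 2.69e-06) and of the intestine genes 0 passed (-0.32, 0.012), both with adjusted p = 0.703 with an estimated correlation. Lysosomal proteases had a median of -0.50 in granulin 2, where cpr-6 and cpr-9 fell (2 alone; 0.00767, adjusted p = 0.964 with an estimated correlation) and -0.64 in granulin 3 with 0 passed (0.022, adjusted p = 0.761 with an estimated correlation). Both protease calls were lost without wild type replicate 4, and each also without 1 other library, granulin 2 replicate 2 or granulin 3 replicate 3. The protease median in granulin 3 was -0.25 without wild type replicate 4 and also without granulin 3 replicate 3. The immune call in granulin 1 was lost without granulin 1 replicate 3, where its median changed sign to -0.05 and that of vitellogenins was -0.995, and the intestine call without wild type replicate 4 (median -0.03). The list count was 11 in granulin 1 without granulin 1 replicate 3 and 4 in granulin 2 without granulin 2 replicate 2. On the deposited scale the intestine median in granulin 1 turned to 0.16 and the protease median in granulin 3 to 0.17, both below the shift of all genes.

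**Figure D5:**
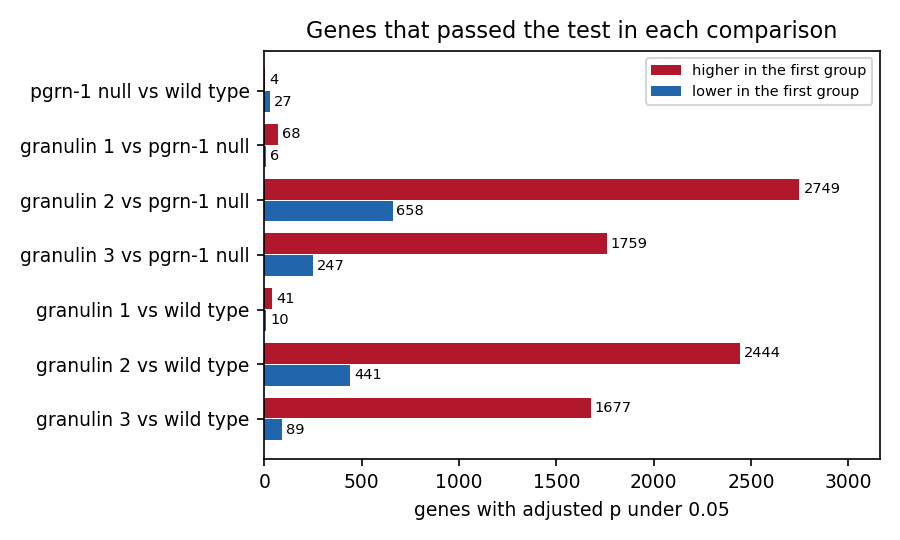
Number of genes higher and lower at an adjusted p under 0.05 (horizontal axis) in the comparisons against wild type or the null (vertical axis). Comparisons between granulin strains are not shown. Counts run from 31 in the null against wild type to 3407 in granulin 2 against the null.

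Direct comparison of the granulin strains separated them at named genes. Granulin 2 exceeded granulin 1 in F15D4.5 by 6.28 ± 0.45 (adjusted p = 2.04e-08) and daam-1 by 5.84 ± 0.70 (1.07e-05), and F11C3.1 fell by 4.75 ± 0.27 (3.99e-10) and ZC317.7 fell by 4.38 ± 0.54 (1.23e-05). Granulin 3 exceeded granulin 1 in clc-1 by 4.87 ± 0.33 (1.47e-08) and cdf-2 by 4.38 ± 0.29 (8.55e-09), and F11C3.1 fell by 4.76 ± 0.27 (7.56e-10). Against granulin 2, granulin 3 was higher in ZC317.7 by 4.68 ± 0.54 (9.91e-06) and F55G11.4 by 3.49 ± 0.50 (0.000165), and F15D4.5 fell by 5.67 ± 0.45 (1.26e-07). Y38E10A.14, with 0 reads in granulin 3, passed against both (adjusted p = 4.94e-11 and 6.24e-10). Limma called 2974 genes between granulin 2 and 1 (2325 higher), 878 between granulin 3 and 1 (837 higher) and 849 between granulin 3 and 2 (271 higher, 31.9%, and 578 lower). Genes without overlap were 19.6%, 8.04% and 13.3%, with 2.86% from chance. In fits of the 2 strains alone the count was 1821 between granulin 2 and 1 and 217 between granulin 3 and 1. The granulin 3 and 1 count was 346 and 270 without granulin 3 replicates 1 and 4, and 419 and 473 without granulin 1 replicates 2 and 4. Between granulin 3 and 2 it was 487 and 1381 without granulin 3 replicates 3 and 4 and 530 without granulin 2 replicate 3, and another split of the same 8 libraries gave 3685 genes. On the deposited scale, with shifts of -0.19, 0.36 and 0.50, the split between granulin 3 and 2 turned to 290 higher (56.4%) and 224 lower, and relative log expression scaling shifted that median by -0.12. With the length covariate 2896 were higher and 2136 lower between granulin 2 and 1, 1570 and 1070 between granulin 3 and 1, and 798 and 1153 between granulin 3 and 2.

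Return toward wild type was counted over genes that differed between the null and wild type. With the null libraries split 2 and 2, so that separate libraries served both comparisons, 10 to 16 genes passed in each of 6 splits. Of these, 81.5% (range 73.3% to 87.5%) had the opposite sign in granulin 1, 88.5% (73.3% to 93.8%) in granulin 2 and 81.5% (73.3% to 87.5%) in granulin 3. Without an effect or a batch the value is 50% among genes with a fold change other than 0. Genes with 0 reads on both sides counted as no return, 2 per split in granulin 1 and 3 and 1 in granulin 2. They put the value without an effect below 50%. The shares include pgrn-1, and without it they were 79.9%, 87.55% and 79.9%. In granulin 1 and 3, whose letters are those of wild type, a batch that follows the letters would by itself give opposite signs. Without the filter on low genes the shares were 55.2% (42.1% to 66.7%), 60.9% (47.4% to 75%) and 55.2% (42.1% to 66.7%), so some splits lay below 50%, and without pgrn-1 they averaged 52.25%, 58.4% and 52.25%. Genes with 0 reads on both sides lower these shares too, so a share below 50% does not by itself show the absence of a return. No test was made of these shares. Y102A5C.36 and fbxa-192, low in the null, are examples that rose in granulin 1, whereas F56A4.3, chosen after its values were seen, had 0 reads in all null libraries and in all 3 granulin strains, and 155 to 289 in wild type.

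Calls against the null were shared between granulin strains. Granulin 1 and 2 shared 53 genes in direction, granulin 1 and 3 shared 62 with 1 opposite, and granulin 2 and 3 shared 1461 with 5 opposite. Independent lists of these sizes would share 11.9 higher and 0.251 lower genes, 7.6 and 0.0942, and 307 and 10.3. With the null libraries split 2 and 2 the shared numbers averaged 27.2 (20 to 35), 30.8 (24 to 39) and 685 (328 to 1041). Each strain was then tested against only 2 null libraries, which by itself lowers the number of calls. The lower shared numbers thus do not measure how much sharing a common null adds. Over all genes, which are not independent replicates, fold changes correlated with r = 0.371, 0.595 and 0.75 and had covariances of 0.291, 0.356 and 1.01. In 50 draws of unchanged groups against a common null group, which was drawn too, 0 genes were shared. In these draws r averaged 0.458 (-0.522 to 0.944) and the covariance 0.134 (SD 0.154). No gene was changed in the draws, so their 0 does not tell how many shared calls a common null adds among real calls. The observed covariances exceed the drawn mean by 0.158, 0.222 and 0.877. With the null libraries split, the covariances averaged 0.206, 0.268 and 0.908 and r averaged 0.234, 0.401 and 0.647.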

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

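Both tests of the length trend in granulin 1 replicate 3 were set before their results were seen, after the trend itself had been noticed. Libraries are listed here where 1 of the 4 of a strain lay far from the other 3 by Dixon's ratio. Chance does so in about 1 in 20 groups, which gives 34.4 of the 689 groups examined, and 76 were found, 23 of them in granulin 1 replicate 3, 19 in null replicate 1 and 17 in wild type replicate 4.

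Among library measures, ribosomal RNA took 44.8% of reads in wild type replicate 4 (others 1.05% to 5.92%), 25.9% in granulin 1 replicate 3 (0.919% to 3.45%) and 8.39% in granulin 3 replicate 2 (0.45% to 1.24%). Mitochondrial reads were 8.09% in granulin 1 replicate 3 (0.726% to 1.43%). The length slope was -0.408 in null replicate 1 (0.0157 to 0.0674) and -1.03 in granulin 1 replicate 3 (-0.0121 to 0.0578).

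Granulin 1 replicate 3 stood apart in the means of 11 lists, in log2 units about the mean of all libraries. They were lysosomal proteases 0.711, other lysosomal hydrolases 1.1, autophagy -1.04, endoplasmic reticulum -1.35, the mitochondrial stress response -0.761, immune effectors 1.49, detoxification 0.661, mitochondrial DNA 2.91, apoptosis -1.2, oocyte genes -3.54, and germline genes -1.61. Its oocyte value lay below 0.745 to 0.854 in the other 3. Null replicate 1 stood apart in lysosomal membrane genes (-0.298), heat shock (-0.12), endoplasmic reticulum (-0.461), the mitochondrial stress response (-0.0768), immune effectors (0.228), oxidative stress (0.0445), ribosomal proteins (-0.169), apoptosis (-0.499), oocyte genes (-0.674) and germline genes (-0.533). Wild type replicate 4 did so in lysosomal proteases (1.2), the respiratory chain (0.594), ribosomal proteins (0.78), the proteasome (-0.376), apoptosis (-0.562) and germline genes (-0.273). Single cases were oxidative stress in granulin 2 replicate 3 (0.238), the respiratory chain in granulin 1 replicate 4 (0.301) and granulin 2 replicate 2 (-0.505), and muscle in granulin 1 replicate 2 (0.16).

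Named genes are given in log2 CPM. In granulin 1 replicate 3, pgrn-1 was at 10 (others 7.79 to 8.15), flp-2 at -0.0719, F11C3.1 at 6.82, F42A10.9 at 3.12, egg-2 at 3.57, fmil-1 at -1.57, acly-2 at 4.58, mans-4 at 4.43 and col-14 at 0.697. In wild type replicate 4, his-35 was at 4.8, asp-3 at 11.3 (others 9.22 to 9.35), rpl-22 at 9.82, rps-16 at 9.13, egg-2 at 5.33, egg-3 at 5.12, ZC317.7 at 1.21, acly-2 at 6.93, rpl-41.1 at 6.51 and K08D9.9 at 3.12. In null replicate 1, egg-2 was at 7, egg-3 at 6.56, acly-2 at 7.58, lipl-5 at 6.53, pas-5 at 9.26, ndab-2 at 7.55, rpl-41.1 at 7.27 and K08D9.9 at 3.4. Y102A5C.36 was at -2.14 in null replicate 3 and unc-47 at -3.68 in null replicate 4. F11C3.1 was at 1.57 in wild type replicate 2, and col-137 at -3.48 in wild type replicate 1. In the other granulin libraries, asg-1 was at 7.4 in granulin 1 replicate 4, spe-19 at -2.92 in granulin 1 replicate 1, rpt-4 at 7.39 in granulin 2 replicate 3, col-46 at -3.26 and rpn-12 at 6.26 in granulin 3 replicate 1, and egl-3 at 3.64 and F55G11.4 at 7.54 in granulin 3 replicate 3.

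Granulin 1 replicate 3 combined low oocyte transcripts with low long transcripts, and both a technical and a biological origin were examined. Its trend with transcript length was also present among 97 muscle, neuron and intestine genes, at a slope of -1.2 (SE 0.136), the value needed if RNA integrity or library preparation gave the trend. The shorter members of the oocyte list were low too, with a median deviation of -4.04 (17 genes) against -5.05 for the longer ones (17 genes), the value needed if these animals held fewer oocytes or embryos. Neither explanation is excluded, and both may hold in this library. Fewer oocytes would not by itself give a length trend in muscle, neuron and intestine genes, but differences between those tissues were not separated from length.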

How the results depend on the processing

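Chosen after the data had been seen were the length slope as a covariate, both kinds of library weights, leaving out the 5 libraries with the lowest length slopes, the deposited scale, a prior count of 0.5, and camera on voom values. The count tests of edgeR and DESeq2 were set aside because the deposited unit is log2, and they were not run. The recovered reads would have allowed them, so how the results depend on this choice is not known. Of the counts and shares that answer a comparison, 218 values under alternatives lay near the value reported and 93 did not. Near means within 1.5 times for counts, and within the SD of the splits for the shares that returned toward wild type. Of the values of single named genes, 2624 kept their direction and side of the threshold, 94 lost their call, 130 gained one and 22 changed sign. In simulated data for granulin 1 against the null, with n = 4 libraries per strain, 0 of 67 genes changed 1.5-fold were called, so the absence of a call does not exclude a change of this size. Unless said otherwise the cause of a change was not tested.

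In the order null against wild type, granulin 1, 2 and 3 against the null, granulin 1, 2 and 3 against wild type, granulin 2 and 3 against granulin 1, and granulin 3 against granulin 2, the genes reported are 31, 74, 3407, 2006, 51, 2885, 1766, 2974, 878 and 849. With the length slope as a covariate they were 277, 138, 6103, 4400, 85, 5090, 2914, 5032, 2640 and 1951. With library weights the counts that moved were 2224, 667, 5899, 6491, 198, 4997, 3269, 2655 (granulin 3 against 1) and 1531 (granulin 3 against 2). The estimate of these weights stopped before it converged, and with weights from a gene-by-gene method the counts were 2305, 824, 7393, 5572, 253, 6627, 2842, 5578, 1969 and 2009. The lowest weights were 0.091 in granulin 1 replicate 3, 0.205 in wild type replicate 4 and 0.276 in granulin 3 replicate 2. On the deposited scale 12 genes passed in the null against wild type, 43 and 2247 in granulin 1 and 2 against the null, 2770 in granulin 3 against wild type and 514 between granulin 3 and 2. Voom gave 19 for the null and 30 for granulin 1 against wild type. Protein-coding genes alone gave 9 for the null against wild type and 43 and 33 for granulin 1 against the null and wild type, where 19, 55 and 45 of the reported calls were still tested. In fits of 2 strains alone, granulin 1 had 25 against the null and 9 against wild type, granulin 2 against 1 had 1821 and granulin 3 against 1 had 217. A prior count of 0.5 gave 514 for granulin 3 against 1, no filter gave 1275 for granulin 3 against 2, and without the 5 libraries these comparisons gave 1479 and 502.

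Leaving out each library in turn gave 12 to 34 genes in the null against wild type, 42 to 92 in granulin 1 and 1140 to 1914 in granulin 3 against the null, 29 to 77 in granulin 1 against wild type, 270 to 1011 in granulin 3 against granulin 1 and 487 to 1381 in granulin 3 against granulin 2. Lists that passed camera ranged from 8 to 15 (13 reported) in granulin 1 and 7 to 19 (12) in granulin 2 against the null, and from 11 to 19 (17) in granulin 1 and 4 to 14 (10) in granulin 2 against wild type. With an estimated correlation 0 lists passed in each of the 7 comparisons. The length covariate gave 6 lists in granulin 1 against the null and 9 in granulin 3 against wild type, no filter gave 20 and 17 in granulin 2 against the null and wild type, and without the 5 libraries 7, 5 and 10 passed in granulin 1 against the null and in granulin 2 and 3 against wild type. Camera on voom values called 10, 14, 12, 16, 20, 9 and 16 lists.

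The shared label letter as a block gave 11 genes in granulin 1 against wild type (14 for the same libraries without it), 2357 in granulin 2 against the null (3673), 1301 in granulin 3 against wild type (1249) and 598 in granulin 3 against granulin 1 (510). Deviations of libraries with the same letter did not all correlate above 0.1 in any of these pairings (-0.59 to 0.284 with 0 of the libraries closest to their own letter, -0.282 to 0.579 with 2 in granulin 1 and wild type, -0.217 to 0.435 with 1, and -0.0929 to 0.501 with 3), so the letters were not taken to pair libraries. This check was seen together with the blocked counts.

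Shared genes with the null libraries split averaged 27.2, 30.8 and 685 for granulin 1 and 2, 1 and 3, and 2 and 3, and without the filter the shares that returned toward wild type were 55.2%, 60.9% and 55.2%. Sign changes concerned asp-3 and lmp-1 only, and none of these values passed. For lmp-1 in the null against wild type (-0.03) the values were 0.00996 with relative log expression scaling, 0.00976 without the filter, 0.15 with the length covariate, 0.24 and 0.25 with the 2 kinds of weights, 0.19 without the 5 libraries, 0.40 on the deposited scale, and 0.0125, 0.0807, 0.195 and 0.022 without wild type replicates 2 and 4 and null replicates 1 and 2 (lowest -0.113 without wild type replicate 3). For asp-3 in the null (-0.43) they were 0.0561 and 0.0591 with weights, 0.00407 on the deposited scale and 0.0685 without wild type replicate 4 (lowest -0.61 without wild type replicate 3). In granulin 1 against the null asp-3 (-0.05) had 0.0763 with the length covariate and 0.0312 without granulin 1 replicate 2 (lowest -0.124 without granulin 1 replicate 3). In granulin 2 asp-3 (-0.17) had 0.26 without the 5 libraries and 0.28 without granulin 2 replicate 2, and lmp-1 (-0.06) had 0.0892 and 0.316 (lowest -0.559 for asp-3 without granulin 2 replicate 4 and -0.289 for lmp-1 without null replicate 1). In granulin 3 asp-3 (-0.64) had 0.16 without the 5 libraries.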

Other observations

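The length covariate, the male neuron genes, both window counts and the pseudogene test were chosen after the results they bear on were seen, as were the genes named here that no rule names.

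Some genes had 0 reads in every library of 1 or more strains. Counts do not tell whether such a gene was silent or differed in the genome of these strains, which was not tested. F56A4.3 had 0 reads in all null libraries and 155 to 289 in wild type, at least 94.1-fold lower with a floor of 3 reads per library, and 0 in all granulin libraries too. ZK228.3 had 0 reads in all granulin 1 and granulin 3 libraries and 318 to 852 in the null, at least 164-fold and 247-fold lower. The chemoreceptor gene sri-12 had 0 reads in the null and was at least 6.43-fold higher in granulin 1, 18.9-fold in granulin 2 and 11.3-fold in granulin 3. Of 266 tested genes with F-box or MATH domain symbols, 3 fell in the null against wild type, 8 rose in granulin 1 against the null, 84 rose and 18 fell in granulin 2, and 37 rose and 7 fell in granulin 3. Among all 15737 tested genes, in the same order, 27 fell, 68 rose, 2749 rose and 658 fell, and 1759 rose and 247 fell. The family was not tested against all genes. Pseudogenes were 584 of 15737 tested genes (3.71%), and 11 of the 31 genes that differed between the null and wild type (35.5%, Fisher's exact test, two-sided, p = 7.21e-09), 17 of 74 in granulin 1 against the null (23%, p = 1.22e-09), 209 of 3407 in granulin 2 (6.13%, p = 1.52e-15) and 5.38% of the 2006 in granulin 3 (p = 6.28e-05). Genes are not independent, and reads of pseudogenes can belong to their parent genes.

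The pan-neuronal gene unc-119 rose over the null by 1.77 ± 0.24 in granulin 2 (limma adjusted p = 1.42e-05) and by 2.4 ± 0.24 in granulin 3 (2.77e-06), and its value in granulin 1 was 0.0879 ± 0.24 (0.94). The median of the 34 neuron genes was 0.61, 0.47 and -0.09 in the same order. Against wild type unc-119 rose by 1.49 ± 0.24 in granulin 2 (limma adjusted p = 5.22e-05) and by 2.13 ± 0.24 in granulin 3 (1.23e-05), with list medians of 0.08 and 0.03. The rise of unc-119 thus does not stand for neuron genes as a set. Gene totals do not tell which part of unc-119 the reads covered, and the cause of its rise was not tested.

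Sperm genes were higher in granulin 2 and granulin 3 than in the null, with list medians of 3.78 and 2.34. A bias of some libraries toward short transcripts was excluded as the whole origin, since with the length slope as a covariate the medians were 3.75 and 2.3, and the lower share kept was 98.3%. Males among the animals were not excluded: the larger median of 7 male neuron genes was 0.605, and without the filter pkd-2 (2.42 ± 0.60, adjusted p = 0.00704) and cwp-5 (1.35 ± 0.45, 0.0441) passed in granulin 2 and cwp-2 (1.1 ± 0.33, 0.0494) in granulin 3, but the highest level of any was 0.511 CPM, too low to decide. For younger animals that still make sperm the prediction was higher fog-1 and fog-3, which set sperm fate early in spermatogenesis, in both strains. Only fog-3 in granulin 2 passed (2.21 ± 0.56, adjusted p = 0.00866). There was no call for fog-1 in granulin 2 (0.215 ± 0.70, 0.901) or for fog-1 and fog-3 in granulin 3 (0.342 ± 0.70, 0.909, and 0.586 ± 0.56, 0.661). These values lay above 0 with wide errors, so the test cannot decide and younger animals are not excluded. An effect of the granulins themselves is untested, because each was carried by 1 strain.

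Some genes were apart from all 4 other strains in a single granulin strain: 463 higher and 67 lower in granulin 2, 49 and 4 in granulin 3, and 2 and 2 in granulin 1 (F11C3.1 and the pseudogene WBGene00005646 higher, D1086.6 and clc-1 lower). In granulin 3, 45 pairs of such genes lay within 100 kb (random draws of tested genes: median 3, highest 13; permutation p = 1e-04, the smallest 10000 draws can give) and the 5 fullest windows of 1 Mb held 58.5% of them, 19 genes between 11 and 12 Mb on chromosome X, such as apt-9 (5.23), pgp-3 (1.49), lev-8 (2.335) and clc-1 (1.61), so differences in a few genome regions of this strain are a candidate explanation. Granulin 2 had 512 such pairs (random median 295, highest 371, permutation p = 1e-04), as predicted beforehand for a few regions. Pairs and windows were counted over the 527 genes with a position in the annotation. The window count, chosen after the pairs were seen, put 15.7% of these genes in its 5 fullest windows (83 genes, random median 56, highest 69). A few regions thus cannot hold most of them, though clustering beyond random draws was there. Random draws do not account for gene families and co-expressed neighbours, so neither count shows what differs in the genome. For granulin 1 the test is void, which was recognised after its value was seen: 4 genes gave 0 pairs, and random draws have a median of 0.

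The 8 libraries of 2 strains were split in 35 ways, in fits of those 2 strains alone. For 9 of the 10 comparisons only 1 split, the real one, gave as many genes. This is the lowest share that 35 splits can give, and it was not adjusted over the 10 comparisons. Mixed splits also hold the strain differences within each group, which widens their spread and lowers their counts. The test thus argues against a chance split for these 9 but cannot exclude one, and it does not separate strain from letter. The real and the highest other counts were 26 and 1 for the null against wild type. Against the null they were 25 and 0 for granulin 1, 3673 and 0 for granulin 2, and 2112 and 0 for granulin 3. Against wild type they were 9 and 0, 2376 and 0, and 1464 and 0, and between granulin strains 1821 and 0 (granulin 2 and 1) and 217 and 0 (granulin 3 and 1). For the number of genes between granulin 3 and granulin 2 chance cannot be excluded by this test: 2 of the 35 splits gave at least the real 819 genes, the other giving 3685, several times as many. That split sets granulin 3 replicates 1 and 4 and granulin 2 replicates 1 and 4 against the rest. These libraries had the higher length slopes and also the higher oocyte list means (0.49 to 1.02, against -1.78 to -0.87). Transcript length and oocyte content were not separated here. With the length slope as a covariate all 849 calls between these strains were kept among 1951, and single genes such as F15D4.5 (-5.67 ± 0.45, adjusted p = 1.26e-07) do not rest on the count. For the number of gene lists chance cannot be excluded in any of the 7 comparisons, with 35, 32, 22, 14, 28, 33 and 19 of 35 splits giving as many lists as the real 7, 12, 13, 16, 15, 8 and 14 (null against wild type, granulin 1, 2 and 3 against the null, granulin 1, 2 and 3 against wild type), and highest others of 22, 22, 22, 22, 24, 22 and 21.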
